A study of Homo sapiens with 24 samples.

How the data were processed

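Gene expression was measured in human OCI-AML3 cells, an established acute myeloid leukaemia line, grown in NSG mice, an immunodeficient strain that accepts human cells. The cells carried luciferase for imaging and GFP for sorting. From each of 8 mice they were sorted on GFP and human CD45 out of femoral bone marrow, spleen and peripheral blood, which gave 24 arrays. Per the labels, treated mice received the CXCR4 inhibitor LY2510924 under the skin at 2.5 mg/kg daily; the sample characteristics spell the compound LY2510294. The 3 mice treated for 24 h were harvested on day 41, the 3 control mice on day 42 and the 2 mice treated for 72 h on day 43, so the harvest day equals the treatment group and cannot be separated from it. The label numbers of the mice run from 1 to 9 without a 7, and the sources used here give no reason.

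Total RNA was amplified in 2 rounds, labelled with biotin and hybridised to Illumina human expression BeadChips with 47231 probes. The authors deposited a table with the mean bead intensity of each probe per array, on a linear scale and without background subtraction, as exported by GenomeStudio, whose version was not given in the sources used here. Beside each intensity the deposited table holds a detection p value, the share of negative control probes at least as bright, in steps of 1 in 770. The deposited series matrix holds background-subtracted intensity: each array equals the first table minus 1 constant, from 49.7 to 64.5, to within 0.02, with no scaling between arrays. Gene symbols came from the platform's listing, in which 30113 probes had 1 symbol, 8 had several and 17110 had none; updating the symbols changed 0 of them. The genome build behind the listing was not given, so no coordinates are printed.

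Intensities were background-corrected with the normal-exponential model fitted through the detection p values, offset by 16, quantile normalised and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3. A probe was kept when its detection p was under 0.01 on at least 3 of the 24 arrays, which left 17116 probes, 13275 of them with 1 symbol. For each gene the kept probe with the highest mean stood for the gene, a choice that concerned the 2430 genes with more than 1 kept probe. This gave 10351 genes for testing. Between 13066 and 15721 probes were detected per array, and median raw signals ran from 56.4 to 79.9. No counting interval applies to arrays, whose number limits the precision.

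All tests were moderated tests of limma with Benjamini-Hochberg adjustment, two-sided, at a threshold of 0.05. The numbers in the titles pair the 3 arrays of each mouse. Deviations from the group means correlated by 0.284 on average over 24 pairs of arrays from 1 mouse. As they sum to 0, this largely sets the -0.162 over 42 pairs from different mice. Site comparisons and the tests of whether site differences depended on treatment used all 24 arrays in 9 groups, with the mouse as a fixed replicate block. The latter were F tests over both differences from marrow at once. Without a replicate block the counts for blood against marrow went from 4981 to 3997 genes (others under processing). Treatment comparisons over all sites used 1 value per mouse, the mean of its 3 arrays. Treatment comparisons within a site used the group means of all 24 arrays. In all, 15 comparisons with a direction and 2 tests of treatment by site were made.

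Shifts of 28 gene lists, for pathways and for markers of cell types that the sort could have left behind, were tested with camera of limma at its preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. Lists with fewer than 5 tested genes were not tested, and adjustment ran over all 375 tests. At the preset correlation 115 tests passed the threshold. With an estimated correlation camera of limma passed 0, with 57 at an unadjusted p under 0.05, and 80 of the 115 also passed fry, which does not compare a list with other genes. Ranges of an adjusted p over alternatives leave the estimated correlation aside. Member counts are given over all genes tested and adjusted over the list alone.

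Genes were named by a rule: CXCR4 and its ligand CXCL12; the 10 largest rises and 10 largest falls among genes past the threshold and changed the same way in every mouse (5 and 5 in comparisons within controls or within a site); and up to 4 members with the smallest p of each list described. Which of the lists to describe was chosen after their results were seen. For treatment comparisons the same way in every mouse means groups that did not overlap. Lists, the naming rule, tests and most alternatives were fixed before the data were examined. A gene detected on no array of 1 side is given as "at least N-fold": each value of that side below the lowest detected value of its array was raised to it before the means were compared. A gene detected on fewer than 50% of the arrays of 1 side keeps its fitted difference, which background limits, with the number of those arrays beside it.

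Alternatives were values without background correction, the series matrix values on a log2 scale with values under 16 set to 16, no filter, detection on all arrays, every probe of a gene, no or a random replicate block, the BeadChip as a covariate, arrays of 1 BeadChip or 1 site, and each mouse left out. Chosen after seeing the data were the fits without blood replicate 8 of the 72 h group, the means of marrow and spleen only, control site differences within BeadChip 2, treatment by site on 1 BeadChip, list tests with the BeadChip, and list tests without the replicate block. The 24 h mice lay on BeadChip 1 with 1 control mouse, and the 72 h mice on BeadChip 2 with 2 control mice.

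In a test on simulated data, 10351 genes with 200 changed, site averages recovered 89% to 91% of changes of 1 on the log2 scale. The shares were 63% for 24 h and 43% for 72 h over all sites, and 36% in 72 h blood. Of changes of 2, each of the 15 comparisons recovered at least 81%, with 5 to 15 false calls. For treatment by site the shares were 31% and 18% of changes of 1, and 86% and 61% of changes of 2, at 24 h and 72 h, with 6 and 3 false calls. In camera 15 of 15 lists shifted by 0.5 and 0 of 15 unshifted ones had an unadjusted p under 0.05. Correlation within lists and spread between groups were not varied, which limits these rates.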

Results

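Human OCI-AML3 leukaemia cells were profiled after they had grown in NSG mice and had been sorted from bone marrow, spleen and blood of the same animals. The 24 arrays cover 3 control mice, 3 mice given a CXCR4 inhibitor for 24 h and 2 mice given it for 72 h, with 1 array per site and mouse. CXCR4 is the receptor for CXCL12, a chemokine that holds haematopoietic and leukaemia cells in the marrow. The series set out to describe how site and CXCR4 inhibition each affect gene expression in these cells. Probes detected per array ranged from 13066 to 15721. Values are normalised log2 intensities; differences carry their standard error from limma, and n counts mice.

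Marrow, spleen and blood arrays of the control mice lay apart and close to their own group, with a lowest correlation between arrays of 0.978 within any control group. Correlations within groups were lower for 24 h blood, from 0.894 to 0.97, and were 0.938 for 72 h spleen and 0.934 for 72 h blood. Along the main axis of variation, which held 44% of the variance, blood replicate 8 of the 72 h group lay farthest from the control marrow arrays. Its mean correlation with those was 0.843.

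**Figure D1:**
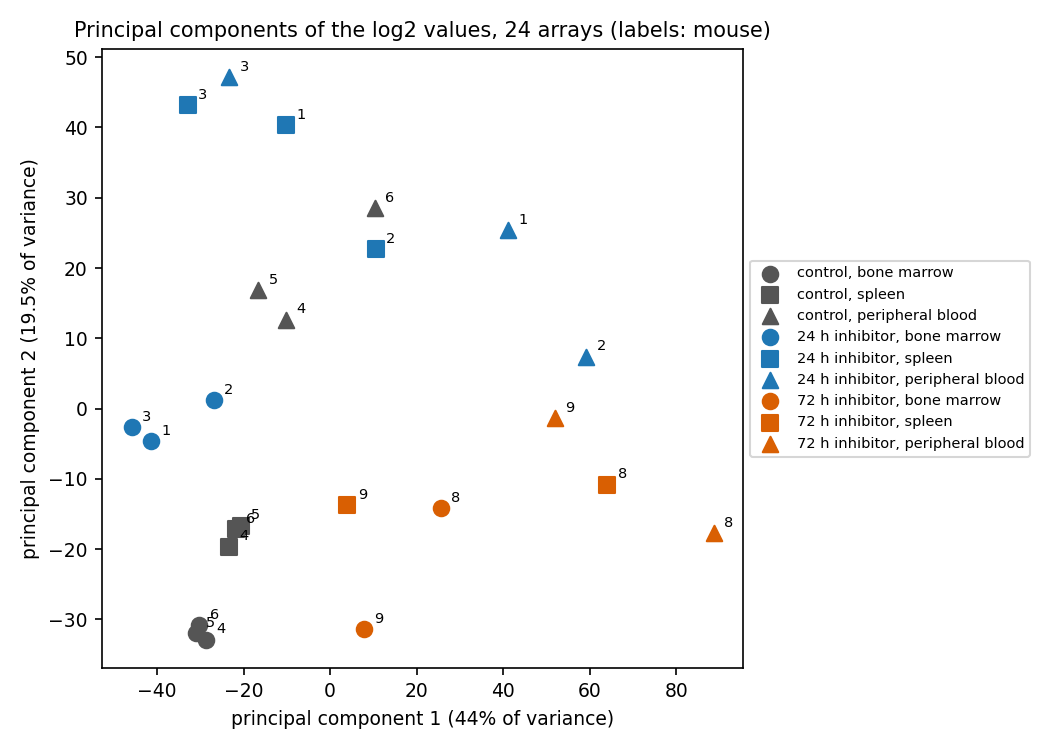
Arrays plotted by their scores on principal component 1 (x axis, 44% of variance) and component 2 (y axis, 19.5%) of the normalised log2 values, coloured by treatment and shaped by site, with the mouse number beside each point. Control marrow arrays sit together at PC1 from -31.1 to -28.7, and blood of mouse 8 at 88.7 is the array farthest from them.

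Blood leukaemia cells differed widely from marrow cells of the same mouse. Over the 3 treatment groups GNLY, the cytolytic granule protein granulysin, was 7.95-fold higher in blood (log2 difference 2.99 ± 0.19, 8 mice, adjusted p = 1.74e-07). CD14, the monocyte co-receptor for endotoxin, was 7.52-fold higher (2.91 ± 0.19, adjusted p = 1.78e-07). EGR1, a transcription factor induced within minutes of growth factor or adhesion signals, was lower in blood in 8 of 8 mice (-2.61 ± 0.21, adjusted p = 1.07e-06). Genes of mitosis, DNA replication and ribosome assembly were lower in blood, and genes of antigen presentation, cholesterol synthesis and mature monocytes were higher. With an estimated correlation between genes these 6 lists did not pass (adjusted p = 0.278 to 0.461).

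The largest rises in blood were of SNORD3C, SNORD3D and SNORD3A, near-identical copies of the U3 small nucleolar RNA gene whose probes may read each other, at log2 differences of 4.67, 4.28 and 3.91. The microtubule protein TPPP3 followed at 3.55 ± 0.23, the LIM protein CRIP2 at 3.40 ± 0.22 and INKA2, an inhibitor of the kinase PAK4, at 3.10 ± 0.26. CAMKV was higher by 2.89 ± 0.15 and LILRA5, an activating receptor of monocytes, by 2.83 ± 0.28 (on 1 of 8 marrow arrays). Among the falls were SNORD100 at -2.36 ± 0.18, the ribosomal protein gene RPL23 at -2.23 ± 0.64 and the kinase-like DIPK1C at -2.05 ± 0.32. RASL11B, a small GTPase, was detected on 0 of 8 blood arrays and was at least 2.21-fold lower there, with means of 5.06 in blood and 7.13 in marrow. Lower too were LINC02910 (-1.93 ± 0.23), MAD2L1 (-1.84 ± 0.35), the DNA helicase BLM (-1.84 ± 0.21), CLSTN2 (-1.83 ± 0.19) and the homeobox gene DLX1 (-1.82 ± 0.14).

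All 26 tested genes of the list for G2/M and mitosis were lower in blood, 26 also when adjusted over the list alone, with a median of -0.96 (adjusted p = 8.77e-10, and adjusted p = 0.396 with estimated correlation). The mitotic kinesin KIF11 fell by 1.48, the centromere histone CENPA by 1.49, the checkpoint kinase BUB1B by 1.35 and DLGAP5 by 1.29. Of 22 genes for G1/S and DNA replication 21 were lower, 22 adjusted over the list alone, with a median of -0.80 (adjusted p = 9.45e-09, and adjusted p = 0.324 with estimated correlation). These included the replicative helicase subunit MCM2 (-0.96 ± 0.10), the ribonucleotide reductase subunit RRM2 (-1.47 ± 0.16, on 1 of 8 blood arrays), UNG (-0.95 ± 0.11) and the thymidylate synthase gene TYMS (-1.35 ± 0.17). Ribosome biogenesis genes fell in 16 of 20 cases, 16 adjusted over the list alone, with a median of -0.86 (adjusted p = 5.09e-07, and adjusted p = 0.278 with estimated correlation). Among them were RRS1 (-1.38 ± 0.14), DKC1 (-0.91 ± 0.10), WDR12 (-0.86 ± 0.09) and MYC itself (-1.49 ± 0.17). Immediate early genes had 2 higher and 8 lower of 20, 2 and 10 adjusted over the list alone, with a median of -0.31 (adjusted p = 0.0392, and adjusted p = 0.558 with estimated correlation). FOS (-1.09 ± 0.11), EGR3 (-1.57 ± 0.19) and JUN (-0.79 ± 0.12) fell beside EGR1. That list no longer passed without mouse 1, 3, 5 or 8, at adjusted p = 0.0644, 0.0722, 0.0616 and 0.082 (median -0.18 without mouse 8), nor on the series matrix values (-0.50, 0.0502) or with probes detected on all arrays (-0.30, 0.118). It did not pass without blood replicate 8 of the 72 h group (0.0552), and over 14 alternatives it ran from 0.00507 to 0.118.

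Antigen presentation genes were higher in blood in 9 of 16 cases and lower in 1, 11 and 3 adjusted over the list alone, with a median of 0.47 (adjusted p = 0.00994, and adjusted p = 0.341 with estimated correlation). The class II genes HLA-DMA (1.95 ± 0.16), HLA-DMB (1.91 ± 0.16) and HLA-DPA1 (2.05 ± 0.18) rose, and the peptide transporter TAP2 fell (-0.81 ± 0.11). Cholesterol synthesis genes rose in 11 of 17 cases, 11 adjusted over the list alone, with a median of 0.58 (adjusted p = 0.000105, and adjusted p = 0.293 with estimated correlation). Examples were MSMO1 (1.15 ± 0.15), TM7SF2 (0.74 ± 0.12), the lanosterol synthase LSS (0.94 ± 0.16) and HMGCS1 (0.58 ± 0.10). Of 23 genes of mature monocytes and granulocytes 14 were higher and 3 lower, 17 and 6 adjusted over the list alone, with a median of 0.59 (adjusted p = 0.000728, and adjusted p = 0.461 with estimated correlation). TREM1 (2.81 ± 0.17), CSF1R, the receptor for macrophage colony-stimulating factor (2.12 ± 0.22), and S100A12 (1.73 ± 0.19, on 3 of 8 marrow arrays) rose with CD14. Chemokine receptor, adhesion and trafficking genes went both ways, 10 higher and 5 lower of 21, 10 and 6 adjusted over the list alone, and the list did not pass (median 0.26, adjusted p = 0.341). In it the chemokine receptor CCR2 fell (-1.66 ± 0.13), and the integrins ITGAL (1.61 ± 0.18) and ITGAX (1.51 ± 0.17) and the selectin ligand SELPLG (1.22 ± 0.17, on 1 of 8 marrow arrays) rose.

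Some markers of cells other than the leukaemia line moved with site. Of 15 erythroid genes on the array the filter kept 5, all lower in blood, 5 adjusted over the list alone. The median was -0.85 (adjusted p = 0.0271, and 0.347 with estimated correlation). FECH (-0.85 ± 0.12) and BPGM (-0.59 ± 0.18) fell. ALAS2 was detected on 6 of 8 marrow and 1 of 8 blood arrays and HBD on 2 and 1, so background limits both. T and NK cell genes had 4 higher and 1 lower of 5 kept out of 14, 4 and 1 adjusted over the list alone. The median was 0.77 (adjusted p = 0.0315, and 0.324 with estimated correlation). GZMB (2.16 ± 0.18, on 2 of 8 marrow arrays) and IL7R (0.77 ± 0.17) rose with GNLY, and GZMA fell (-1.75 ± 0.36). The erythroid list no longer passed without mouse 8 (adjusted p = 0.0546, and 0.00965 to 0.185 over 13 alternatives), nor the T and NK list without mouse 3 (0.0543) or 8 (0.0615, and 0.0195 to 0.165) or without blood replicate 8 of the 72 h group (0.0631). Without the filter neither passed, with medians of -0.01 and 0.01 (adjusted p = 0.185 and 0.165). Of 7 tissue macrophage genes 2 rose and 2 fell, 2 and 2 adjusted over the list alone, with a median of 0.02 (adjusted p = 0.744): C1QB at 1.44 ± 0.27 (on 1 of 8 marrow arrays), MARCO at 0.55 ± 0.17, CD163 at -0.79 ± 0.23 and SLC40A1 at -0.65 ± 0.14 (on 3 of 8 blood arrays). The mean of 4 small RNA genes (SNORD3A, SNORD3C, SNORD3D and RN7SK) was 11.56 ± 0.47 (SD, n = 3) in control blood and 8.69 ± 0.60 in control marrow.

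In numbers, 4981 of 10351 genes passed, 2219 higher and 2762 lower in blood, and 2362 of them changed the same way in all 8 mice. All 21 named genes that passed, CXCR4 included, also passed without each mouse in turn. Within BeadChip 1 the count was 710 (428 higher, 282 lower) and within BeadChip 2 it was 1738 (843 higher, 895 lower). On the unscaled series matrix values, where the median of all genes stood at -0.22, 28.2% of the 2997 genes called were higher in blood, against 44.5% after normalisation.

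Spleen cells differed from marrow cells in fewer genes than blood cells did. SPINT2, an inhibitor of serine proteases, was 6.78-fold higher in spleen than in marrow (2.76 ± 0.21, 8 mice, adjusted p = 5.51e-06), and GNLY was 4.99-fold higher (2.32 ± 0.19, adjusted p = 6.68e-06). RETNLB, a resistin-like secreted protein, was detected on 8 of 8 marrow arrays and 0 of 8 spleen arrays and was at least 6.87-fold lower in spleen, with means of 5.09 and 8.68. As lists, monocyte and antigen presentation genes were higher in spleen and replication and ribosome genes lower, with 8 of 23, 4 of 16, 8 of 22 and 7 of 20 members past the threshold. With an estimated correlation these 4 lists did not pass (adjusted p = 0.278 to 0.396).

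Further rises in spleen were of CRIP2 (2.45 ± 0.22), TPPP3 (2.39 ± 0.23), LILRB2 (1.92 ± 0.21), the transcription factor RUNX3 (1.92 ± 0.11), CD14 (1.90 ± 0.19), PPM1L (1.88 ± 0.10), SMAD6 (1.86 ± 0.14) and SLC11A1 (1.86 ± 0.21, on 2 of 8 marrow arrays). DIPK1C (-2.36 ± 0.32), TMT1B (-2.27 ± 0.23), RASL11B (-1.93 ± 0.23, on 1 of 8 spleen arrays), CLSTN2 (-1.85 ± 0.19) and ALKAL1, a ligand of the ALK receptor (-1.69 ± 0.15, on 3 of 8 spleen arrays), fell. So did EGR3 (-1.57 ± 0.19), ST3GAL6 (-1.55 ± 0.30), WWC1 (-1.54 ± 0.30) and the cytokine gene OSM (-1.46 ± 0.24). G1/S and replication genes were lower in 8 of 22 cases, 14 adjusted over the list alone, with a median of -0.36 (adjusted p = 2.99e-08, and adjusted p = 0.324 with estimated correlation). Lower were MCM2 (-0.59 ± 0.10), UNG (-0.51 ± 0.11), CDC45 (-0.57 ± 0.14) and FEN1 (-0.47 ± 0.12). Ribosome biogenesis genes were lower in 7 of 20, 15 adjusted over the list alone, with a median of -0.37 (adjusted p = 3.96e-07, and adjusted p = 0.278 with estimated correlation). Lower in this list were WDR12 (-0.54 ± 0.09), MYBBP1A (-0.84 ± 0.16), NOLC1 (-0.73 ± 0.15) and NOP16 (-0.65 ± 0.14).

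Mature monocyte genes were higher in spleen in 8 of 23 cases and lower in 1, 12 and 2 adjusted over the list alone, with a median of 0.38 (adjusted p = 0.000102, and adjusted p = 0.396 with estimated correlation). CSF1R (1.45 ± 0.22), the co-stimulatory ligand CD86 (1.11 ± 0.17) and TREM1 (1.02 ± 0.17) rose with CD14. Antigen presentation genes were higher in 4 of 16, 6 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.00261, and adjusted p = 0.293 with estimated correlation): HLA-DPA1 (1.44 ± 0.18), HLA-DMB (1.30 ± 0.16), HLA-DMA (1.22 ± 0.16) and TAP1 (0.50 ± 0.12). T and NK cell genes had 3 higher and 1 lower of 5, 4 and 1 adjusted over the list alone, with a median of 0.50 (adjusted p = 0.013, and adjusted p = 0.282 with estimated correlation). Among these GZMB stood at 1.15 ± 0.18 (on 2 of 8 marrow arrays), NKG7 at 0.45 ± 0.14 and GZMA at -1.60 ± 0.36. In total 1123 genes passed, 649 higher and 474 lower in spleen, and 716 changed the same way in all 8 mice. The count was 15 within BeadChip 1, 29 within BeadChip 2, 505 without a replicate block, and 679, 575, 508 and 651 without mouse 1, 4, 5 or 6. Of 404 genes called on the series matrix values, whose median over all genes was 0.17, 88.1% were higher in spleen, against 57.8%.

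Between blood and spleen, the SNORD3 copies again differed most, with SNORD3C, SNORD3D and SNORD3A higher in blood by 3.88, 3.57 and 3.24 (adjusted p = 1.29e-05, 7.39e-06 and 7.39e-06). NEUROG2, a neurogenic transcription factor, fell by 2.10 and the Notch target HES1 fell by 1.67 in blood (on 2 and 3 of 8 arrays). The cytokine gene IL19 was detected on 0 of 8 blood arrays and was at least 1.66-fold lower there, at means of 4.65 in blood and 6.71 in spleen. Mitosis genes were lower in blood than in spleen and cholesterol synthesis genes were higher as lists, which did not pass with an estimated correlation (adjusted p = 0.391 and 0.282).

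SNORA16A, detected on 8 of 8 blood arrays and 0 of 8 spleen arrays, was at least 2.45-fold higher in blood (means 7.19 and 4.92), and RETNLB, also undetected in spleen, at least 1.85-fold higher (6.79 and 5.09). INKA2 (2.10 ± 0.26), FILIP1L (1.98 ± 0.16, on 1 of 8 spleen arrays), TREM1 (1.79 ± 0.17), IER5L (1.75 ± 0.15, on 1 of 8) and DUSP8 (1.57 ± 0.16) rose. SNORD100 (-1.81 ± 0.18), CYCSP52 (-1.50 ± 0.27, on 2 of 8 blood arrays), CXCL1 (-1.40 ± 0.17), LINC02910 (-1.38 ± 0.23), ANLN (-1.37 ± 0.19), GPSM2 (-1.31 ± 0.27) and SLC22A15 (-1.29 ± 0.26) fell. Of 26 mitosis genes 19 were lower in blood, 22 adjusted over the list alone, with a median of -0.73 (adjusted p = 2.55e-10, and adjusted p = 0.391 with estimated correlation). They included KIF11 (-1.12 ± 0.17), CENPA (-1.13 ± 0.17), BUB1B (-0.97 ± 0.16) and NUSAP1 (-0.87 ± 0.15). Cholesterol synthesis genes were higher in 8 of 17, 10 adjusted over the list alone, with a median of 0.35 (adjusted p = 4.48e-05, and adjusted p = 0.282 with estimated correlation). Higher were MSMO1 (0.78 ± 0.15), TM7SF2 (0.62 ± 0.12), CYP51A1 (0.58 ± 0.11) and MVK (0.58 ± 0.13). Erythroid genes were lower in blood in 5 of 5, 5 adjusted over the list alone, with a median of -0.91 (adjusted p = 0.00157, and adjusted p = 0.278 with estimated correlation). BPGM stood at -0.91 ± 0.18 and FECH at -0.56 ± 0.12. HBD and ALAS2 were each detected on 1 of 8 blood arrays and on 4 and 6 of 8 spleen arrays. In total 2264 genes passed, 918 higher and 1346 lower in blood, 793 of them the same way in all 8 mice. The count was 5 within BeadChip 1 (5 higher), 182 within BeadChip 2 (101 higher, 81 lower), 892 without a replicate block, and 1312, 1161 and 1431 without mouse 1, 4 or 5 and 794 without mouse 6. Of 2373 genes called on the series matrix values, whose median over all genes was -0.40, 4.0% were higher in blood, against 40.5%.

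In untreated mice a group of genes differed widely between sites. EMP1, an epithelial membrane protein, was 45.0-fold higher in control blood than in control marrow (5.49 ± 0.37, 3 mice, adjusted p = 5.08e-07), CRIP2 57.5-fold (5.84 ± 0.35, adjusted p = 1.45e-07) and GNLY 43.5-fold (5.44 ± 0.30, adjusted p = 1.07e-07). The imprinted non-coding RNA H19 and the tetraspanin CD9 were detected on 0 of 3 control marrow arrays and were at least 35.0-fold (means 11.03 and 5.74) and 19.0-fold (10.14 and 5.15) higher in blood. Spleen held intermediate levels: in spleen H19 was at least 17.0-fold, CRIP2 13.6-fold, GNLY 13.3-fold, EMP1 9.54-fold and CD9 at least 5.49-fold higher than in marrow, with spleen means of 9.99 for H19 and 8.36 for CD9.

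EGR1 (-2.93 ± 0.34), DIPK1C (-2.85 ± 0.52), TMT1B (-2.74 ± 0.37) and DHRS3 (-2.34 ± 0.39) were lower in control blood than in marrow. SNORD14C, detected on 0 of 3 blood arrays, was at least 2.43-fold lower (means 4.92 and 7.13). From marrow to spleen DHRS3 (-2.97 ± 0.39), TMT1B (-2.28 ± 0.37), ALKAL1 (-1.94 ± 0.24), the activin antagonist FST (-1.88 ± 0.37) and the adhesion molecule NCAM2 (-1.48 ± 0.19) fell. From spleen to blood SNORD3C (3.62 ± 0.53), SNORD3D (3.57 ± 0.45), SNORD3A (3.27 ± 0.41) and INKA2 (2.56 ± 0.42) rose, and RETNLB was at least 3.18-fold higher (means 7.53 and 5.02). HBA2 (-2.41 ± 0.64), EGR1 (-2.33 ± 0.34) and SNORD100 (-1.72 ± 0.28) fell, while ALAS2 (at least 1.82-fold lower, means 4.60 in blood and 6.71 in spleen) and SNORD14D (at least 2.73-fold lower, 5.24 and 7.30) were not detected in control blood. Mitosis genes were lower in control blood in 21 of 26 against marrow, 26 adjusted over the list alone (median -1.05, -0.60 without mouse 6, adjusted p = 4.32e-11, and adjusted p = 0.361 with estimated correlation). CENPA stood at -1.22 ± 0.28, DLGAP5 at -1.21 ± 0.28, CDK1 at -1.15 ± 0.27 and KIF11 at -1.13 ± 0.27. Against spleen 13 of 26 were lower, 26 adjusted over the list alone (median -1.01, -0.63 without mouse 6, adjusted p = 6.43e-16, and adjusted p = 0.285 with estimated correlation), with CENPA at -1.54 ± 0.28 and TOP2A at -1.36 ± 0.30. Antigen presentation genes were higher in control blood than marrow in 6 of 16, 9 higher and 2 lower adjusted over the list alone (median 0.54, adjusted p = 0.00129, and adjusted p = 0.282 with estimated correlation), led by HLA-DPA1 at 3.28 ± 0.28, HLA-DMA at 2.65 ± 0.26, HLA-DMB at 2.60 ± 0.26 and HLA-DRA at 1.01 ± 0.17. In control spleen 3 of 16 were higher than in marrow, 3 adjusted over the list alone (median 0.26, adjusted p = 1.83e-05, and adjusted p = 0.278 with estimated correlation). T and NK genes had 3 higher and 1 lower of 5 in control blood, 3 and 1 adjusted over the list alone (median 1.81, adjusted p = 0.00239, and adjusted p = 0.278 with estimated correlation), with GZMB, undetected in control marrow, at least 3.69-fold higher (means 7.79 and 4.84), IL7R at 1.81 ± 0.27 and GZMA at -1.85 ± 0.58.

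The control counts were 1684 genes between blood and marrow (933 higher, 751 lower), 58 between spleen and marrow (47 and 11) and 593 between blood and spleen (378 and 215). Within BeadChip 2, which held 2 of the 3 control mice, they were 510, 13 and 41, and BeadChip 1 held 1 control mouse, too few for a value. Without a replicate block they were 1037, 16 and 171. Without control mouse 4, 5 or 6 the counts were 786, 614 and 309, then 20, 17 and 21, then 64, 113 and 14, in that order. Without mouse 8 or 9 the last was 1032 in each case, and without blood replicate 8 of the 72 h group it was 905. On the series matrix values the percent higher was 66.8 in place of 55.4 between blood and marrow and 83.3 in place of 63.7 between blood and spleen, with medians of all genes at -0.13 and -0.20.

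**Figure D2:**
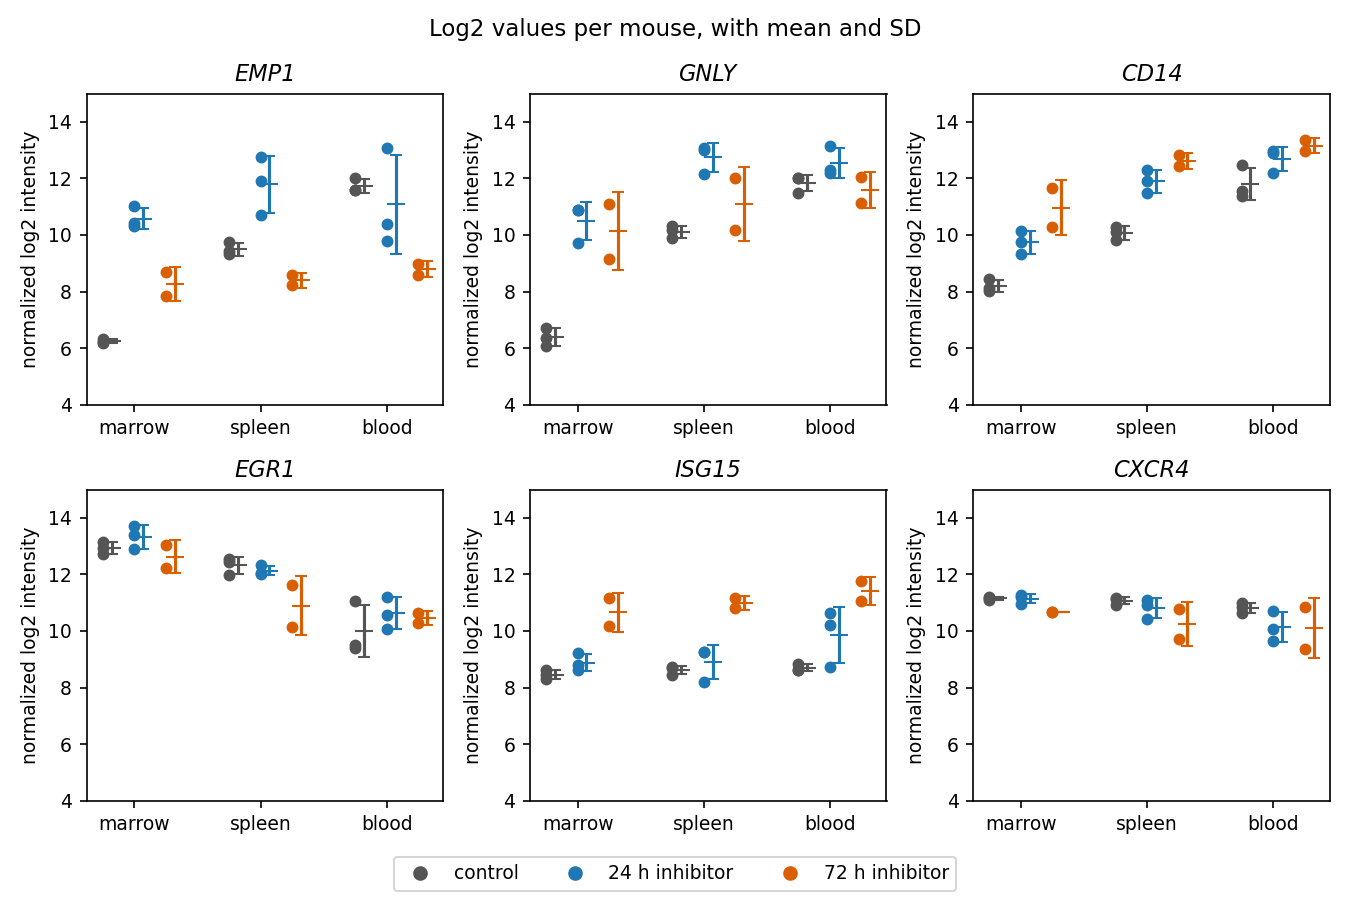
Normalised log2 intensity (y axis) of EMP1, GNLY, CD14, EGR1, ISG15 and CXCR4 in each array by site and treatment (x axis); points are single mice, bars the mean with its SD. EMP1 in marrow averaged 6.24 in control mice and 10.57 after 24 h, and ISG15 over all sites averaged 8.59 in control mice and 11.01 at 72 h.

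After 24 h of CXCR4 inhibition, averaged over the 3 sites, GNLY was 5.58-fold higher than in control mice (2.48 ± 0.36, 3 mice per group, adjusted p = 0.0239). The stress-response genes ATF3 (1.70 ± 0.23, adjusted p = 0.0227) and HMOX1, the heme-degrading enzyme (1.65 ± 0.18, adjusted p = 0.0215), were higher too. Mitosis and replication genes were lower as lists, and NF-kB, p53 target and cholesterol synthesis genes higher, although at most 1 member of each list passed singly. With an estimated correlation these 5 lists did not pass (adjusted p = 0.278 to 0.396). The effect cannot be separated from harvest day.

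CD9 (2.06 ± 0.36), H19 (2.00 ± 0.25), the growth factor binding protein IGFBP3 (1.96 ± 0.26), CRIP2 (1.66 ± 0.24), the lysosomal thiol reductase IFI30 (1.54 ± 0.22), LMNA (1.47 ± 0.15) and the adenosine receptor ADORA2A (1.46 ± 0.16) rose. The GTPase RAC3 (-1.78 ± 0.22), DIPK1C (-1.55 ± 0.26), INCENP (-1.55 ± 0.23, on 1 of 9 treated arrays), SLC22A16 (-1.48 ± 0.20) and ZNF428 (-1.30 ± 0.20) fell. So did PDYN (-1.29 ± 0.13), NPM3 (-1.21 ± 0.22), PLD6 (-1.19 ± 0.19), DMRT3 (-1.18 ± 0.17, on 2 of 9) and CENPF (-1.16 ± 0.18, adjusted p = 0.0258). CXCR4 did not pass (-0.31 ± 0.24, adjusted p = 0.529).

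Mitosis genes had a median of -0.67 at 24 h (adjusted p = 5.7e-13, and 0.396 with estimated correlation). Of 26, 1 was lower over all genes and 23 adjusted over the list alone. The median was -0.85 with the BeadChip covariate, by design the same as within BeadChip 1. CDC20 stood at -1.10 ± 0.22 (adjusted p = 0.0544), NUSAP1 at -0.87 ± 0.18 and PLK1 at -1.06 ± 0.23 (on 4 of 9 treated arrays). G1/S and replication genes had a median of -0.51 (adjusted p = 7.2e-10, and adjusted p = 0.329 with estimated correlation), with 1 of 22 lower, 17 adjusted over the list alone, and -0.52 in both BeadChip fits. In that list the chromatin assembly factor CHAF1A fell (-1.03 ± 0.18, adjusted p = 0.044), GINS2 stood at -0.86 ± 0.19 and RRM1 at -0.74 ± 0.19. NF-kB and inflammatory genes had a median of 0.46 (adjusted p = 5.93e-05, and adjusted p = 0.278 with estimated correlation), with 1 of 19 higher, 5 adjusted over the list alone, and 0.34 in both BeadChip fits. TNFAIP2 rose (1.03 ± 0.18, adjusted p = 0.0434), and CD83 (1.12 ± 0.21), CCL3 (0.60 ± 0.14) and IL1B (0.68 ± 0.16) did not pass. For p53 target genes the median was 0.36 (adjusted p = 0.000102, and adjusted p = 0.278 with estimated correlation), with 0 of 17 past limma's threshold over all genes, 4 adjusted over the list alone, and 0.47 in both BeadChip fits. TP53INP1 stood at 0.83 ± 0.16 (adjusted p = 0.0502), TP53I3 at 0.75 ± 0.16 and the cell cycle inhibitor CDKN1A at 0.86 ± 0.22. Cholesterol synthesis genes had a median of 0.35 (adjusted p = 1.44e-05, and adjusted p = 0.351 with estimated correlation), with 0 of 17 over all genes, 5 adjusted over the list alone, 0.53 without mouse 3 and 0.45 in both BeadChip fits. INSIG1 stood at 0.58 ± 0.13, MSMO1 at 0.68 ± 0.15 and LSS at 0.68 ± 0.17.

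Of 10351 genes 93 passed at 24 h, 58 higher and 35 lower. With the BeadChip as a covariate limma called 0, with 1024 at an unadjusted p under 0.05, and within BeadChip 1 it called 0, with 686. It called 0 without mouse 1, 4, 5 or 6, with 1275, 1162, 1259 and 1406 at an unadjusted p under 0.05, but 345 without mouse 2 (123 higher, 222 lower), 344 without mouse 3 and 186 without mouse 8 or 9. With a random replicate block it called 543, and 1204 from marrow and spleen alone (625 higher, 579 lower). On the series matrix values 0 passed, with 1537 at an unadjusted p under 0.05 and a median of all genes at -0.19.

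Within marrow at 24 h EMP1 was 20.2-fold higher (4.34 ± 0.58, 3 mice per group, adjusted p = 0.000569), at 10.57 ± 0.38 (SD) against 6.24 ± 0.07, and GNLY 17.2-fold (4.10 ± 0.49, adjusted p = 0.000166). H19 was at least 13.9-fold higher (means 9.70 and 5.74), IGFBP3 at least 8.54-fold (8.99 and 5.65) and CD9 at least 7.35-fold (8.78 and 5.15). All 22 genes that passed were higher and 0 were lower by limma, among 958 at an unadjusted p under 0.05, but with the marrow arrays alone 217 were higher and 302 lower. TGF-beta and BMP response genes had a median of 0.57 (adjusted p = 0.00401, and adjusted p = 0.278 with estimated correlation), with 0 of 11 past limma's threshold over all genes and 2 adjusted over the list alone, and 0.46 and 0.43 in the covariate and BeadChip 1 fits. ID2 stood at 0.97 ± 0.28, TGIF1 at 0.96 ± 0.33 and SMAD7 at 1.47 ± 0.55. That list did not pass without mouse 2 (median 0.34, adjusted p = 0.0522) or with probes detected on all arrays (0.055, and 0.000239 to 0.055 over 15 alternatives). NF-kB genes had a median of 0.37 (adjusted p = 0.01, and adjusted p = 0.285 with estimated correlation), with 0 of 19 over all genes and 1 adjusted over the list alone, but did not pass with the covariate (0.29, adjusted p = 0.253) or within BeadChip 1 (0.29, adjusted p = 0.0907), nor with probes detected on all arrays (0.26, adjusted p = 0.0789; 0.00155 to 0.253 over 15 alternatives). CD83 stood at 1.23 ± 0.35, CCL2 at -0.74 ± 0.27 and NFKBIA at 0.83 ± 0.31. TNFAIP2 was detected on 1 of 3 treated and 0 of 3 control arrays. The count was 10 with the BeadChip covariate and 0 within BeadChip 1 (332 at an unadjusted p under 0.05), with EMP1 at 4.14 (adjusted p = 0.0136) and 4.26 (adjusted p = 0.999), and 1 control mouse in the second fit. The count was 519 with the marrow arrays alone, 9 on the series matrix values (median of all genes -0.13), 11, 10, 7, 8 and 7 without mouse 1, 2, 4, 5 or 6, 62 without mouse 3 (55 higher, 7 lower) and 49 without mouse 8 or 9.

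In spleen at 24 h CTSV, a cysteine protease, fell by 2.12 (adjusted p = 8.76e-05, 3 mice per group) and SLC22A16 by 2.42 (adjusted p = 0.000164). DIPK1C, detected on 0 of 3 treated arrays, was at least 5.59-fold lower (means 5.43 and 8.38). RAC3 (-2.23 ± 0.54) and LRP3 (-2.20 ± 0.44) also fell, while the tight junction gene CLDN5 (3.03 ± 0.61, on 1 of 3 control arrays), NEUROG2 (2.94 ± 0.70), GNLY (2.62 ± 0.49), CD9 (2.59 ± 0.58) and ADM (2.53 ± 0.54) rose. CLDN5 was also a stroma and endothelium marker (1 of 2 rose). GNLY was also a T and NK marker (1 of 5 rose). Mitosis genes were lower in 15 of 26, 23 adjusted over the list alone, with a median of -1.05 (adjusted p = 3.96e-12, and adjusted p = 0.324 with estimated correlation; -1.23 and -1.09 in the covariate and BeadChip 1 fits). These included CENPF (-1.61 ± 0.27), CCNB1 (-1.33 ± 0.29), CDC20 (-1.60 ± 0.35) and AURKA (-1.04 ± 0.23). G1/S genes were lower in 15 of 22, 17 adjusted over the list alone, with a median of -0.91 (adjusted p = 8.58e-11, and adjusted p = 0.278 with estimated correlation; -0.87 in both BeadChip fits). GINS2 (-1.57 ± 0.25), MCM2 (-1.12 ± 0.20), FEN1 (-1.10 ± 0.22) and UNG (-0.92 ± 0.19) fell. Ribosome biogenesis genes were lower in 10 of 20, 15 adjusted over the list alone, with a median of -0.82 (adjusted p = 3.05e-07, and adjusted p = 0.278 with estimated correlation; -0.91 and -0.87 in the BeadChip fits). The snoRNP methyltransferase FBL (-1.30 ± 0.23), NOP16 (-1.20 ± 0.24), NOLC1 (-1.08 ± 0.25) and DKC1 (-0.79 ± 0.18) fell. Target genes of p53 were higher in 6 of 17, 7 adjusted over the list alone, with a median of 0.57 (adjusted p = 3.6e-05, and adjusted p = 0.278 with estimated correlation; 0.70 and 0.65 in the BeadChip fits). CDKN1A (1.62 ± 0.32), TP53INP1 (1.29 ± 0.30), TP53I3 (1.00 ± 0.23) and PHLDA3 (1.43 ± 0.36) rose. In spleen 1295 genes passed, 678 higher and 617 lower. The count was 929 with the BeadChip covariate and 0 within BeadChip 1 (1216 at an unadjusted p under 0.05), 812 with the spleen arrays alone, 189 on the series matrix values, and 453, 339, 432 and 470 without mouse 1, 4, 5 or 6.

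In blood 4 genes passed at 24 h. DDIT3, the stress transcription factor CHOP, was 4.07-fold higher (2.02 ± 0.30, 3 mice per group, adjusted p = 0.00951) and ARIH2OS 3.16-fold (1.66 ± 0.28, adjusted p = 0.0275). POU2F3 and NFIX, both transcription factors, were not detected on the treated arrays and were at least 1.13-fold (means 4.96 and 6.23) and 1.37-fold (5.38 and 6.51) lower. Heat shock and chaperone genes had a median of 0.52 (adjusted p = 1.28e-08, and adjusted p = 0.278 with estimated correlation), with 0 of 16 past limma's threshold over all genes and 7 adjusted over the list alone, and 0.59 and 0.58 in the covariate and BeadChip 1 fits. The co-chaperone BAG3 stood at 2.01 ± 0.39 (adjusted p = 0.0631), DNAJB1 at 1.38 ± 0.29, HSPA1A at 1.39 ± 0.34 and HSPH1 at 1.24 ± 0.31. NF-kB genes had a median of 0.44 (adjusted p = 0.000158, and adjusted p = 0.278 with estimated correlation), with 0 of 19 over all genes and 3 adjusted over the list alone, and 0.22 and 0.27 in the BeadChip fits. IL1B stood at 0.90 ± 0.30, SOD2 at 0.58 ± 0.19 and TNF at 0.89 ± 0.32, and the list did not pass without mouse 3 (adjusted p = 0.0574, and 3.3e-08 to 0.0574 over 15 alternatives). Of the 10351 genes 1510 had an unadjusted p under 0.05. The gene count was 1 with the BeadChip covariate, 0 within BeadChip 1 (502 at an unadjusted p under 0.05) and 0 with the blood arrays alone (664). It was 2 on the series matrix values (median of all genes -0.44), 1 without mouse 1, 5 or 6, 0 without mouse 4 (742), 1668 without mouse 3 and 54 without mouse 8 or 9.

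At 72 h, averaged over the sites, 9 of 23 interferon-stimulated genes were higher than in control mice. The list did not pass with an estimated correlation (adjusted p = 0.573) or without mouse 9 (median 0.21, adjusted p = 0.268). ISG15, the ubiquitin-like modifier, was 5.37-fold higher (2.42 ± 0.30, 2 treated and 3 control mice, adjusted p = 0.0113), IFI27 10.7-fold (3.41 ± 0.56, on 4 of 9 control arrays, adjusted p = 0.0223) and IFITM3 6.13-fold (2.62 ± 0.35, adjusted p = 0.0163). CD14 was 4.68-fold higher (2.23 ± 0.24, adjusted p = 0.00976). The transcriptional repressor ZEB2 (-2.86 ± 0.57) and the RNA-binding proteins HNRNPH2 (-2.69 ± 0.53) and HNRNPK (-2.48 ± 0.43) were lower.

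The troponin gene TNNT1 (2.50 ± 0.47), S100A12 (2.39 ± 0.57), IGFBP5 (2.33 ± 0.36), HES4 (2.30 ± 0.40), SLC11A1 (2.20 ± 0.70) and the delta globin gene HBD (2.14 ± 0.30, on 1 of 9 control arrays) rose. RPL23 (-3.28 ± 0.97), LINC02910 (-2.44 ± 0.38), HSD17B11 (-2.43 ± 0.48), PRRC2C (-2.40 ± 0.44), TADA1 (-2.36 ± 0.48), AMD1 (-2.32 ± 0.30) and GASK1B (-2.32 ± 0.44) fell. CXCR4 did not pass (-0.67 ± 0.27, adjusted p = 0.0907). Of 23 interferon-stimulated genes 9 rose and 0 fell by limma, 9 adjusted over the list alone. Their median was 0.68 (adjusted p = 0.00028, and 0.573 with estimated correlation). It was 0.77 in both BeadChip fits, the same by design. IRF7 (1.05 ± 0.20) and IFIT3 (1.48 ± 0.28) rose. The list had a median of 1.18 without mouse 8 and did not pass without mouse 9 (median 0.21, adjusted p = 0.268, and 1.87e-13 to 0.268 over 15 alternatives). Antigen presentation genes rose in 5 of 16, 9 adjusted over the list alone, with a median of 0.70 (adjusted p = 0.00349, and adjusted p = 0.293 with estimated correlation), 0.68 in both BeadChip fits and 0.45 without mouse 8: TAPBP (0.78 ± 0.15), TAP1 (0.89 ± 0.21), CD74 (1.34 ± 0.32) and PSMB8 (0.74 ± 0.22). Mature monocyte genes had 8 higher and 2 lower of 23, 11 and 2 adjusted over the list alone, with a median of 0.59 (adjusted p = 0.0392, and adjusted p = 0.521 with estimated correlation) and 0.55 in both BeadChip fits. TLR4 (1.76 ± 0.25, on 3 of 9 control arrays) and TREM1 (1.87 ± 0.37) rose and TLR2 fell (-0.90 ± 0.20, on 1 of 6 treated arrays). This list did not pass without mouse 5 (adjusted p = 0.0609) or 9 (0.164), nor with probes detected on all arrays, where the median was 0.24 (adjusted p = 0.263), with 0.000171 to 0.263 over 15 alternatives. Of the erythroid markers HBD and ALAS2 (2.05 ± 0.61, on 4 of 9 control arrays) rose and FECH fell (-0.67 ± 0.21), 3 and 2 adjusted over the list alone, with a median of 1.13 (adjusted p = 0.455; 1.32 in both BeadChip fits). Without mouse 8 the list passed (adjusted p = 0.0348, and 0.0348 to 0.647 over 14 alternatives).

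At 72 h 2426 genes passed, 1049 higher and 1377 lower. With the BeadChip as a covariate the count was 1, with 3264 at an unadjusted p under 0.05, and within BeadChip 2 limma called 0, with 3787. Without mouse 4 the count was 1, without mouse 5 or 6 it was 0 (3347 and 3550 at an unadjusted p under 0.05), without mouse 8 17 (17 higher), without mouse 1 1125 and without mouse 3 3827. It was 912 without the filter (500 higher, 412 lower). Of 1768 genes called on the series matrix values 7.9% were higher, against 43.2%, with a median of all genes at -0.34. The small RNA mean was 9.35 ± 0.08 (SD, n = 2) in 72 h marrow, 10.60 ± 1.67 in spleen and 13.29 ± 1.10 in blood.

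**Figure D3:**
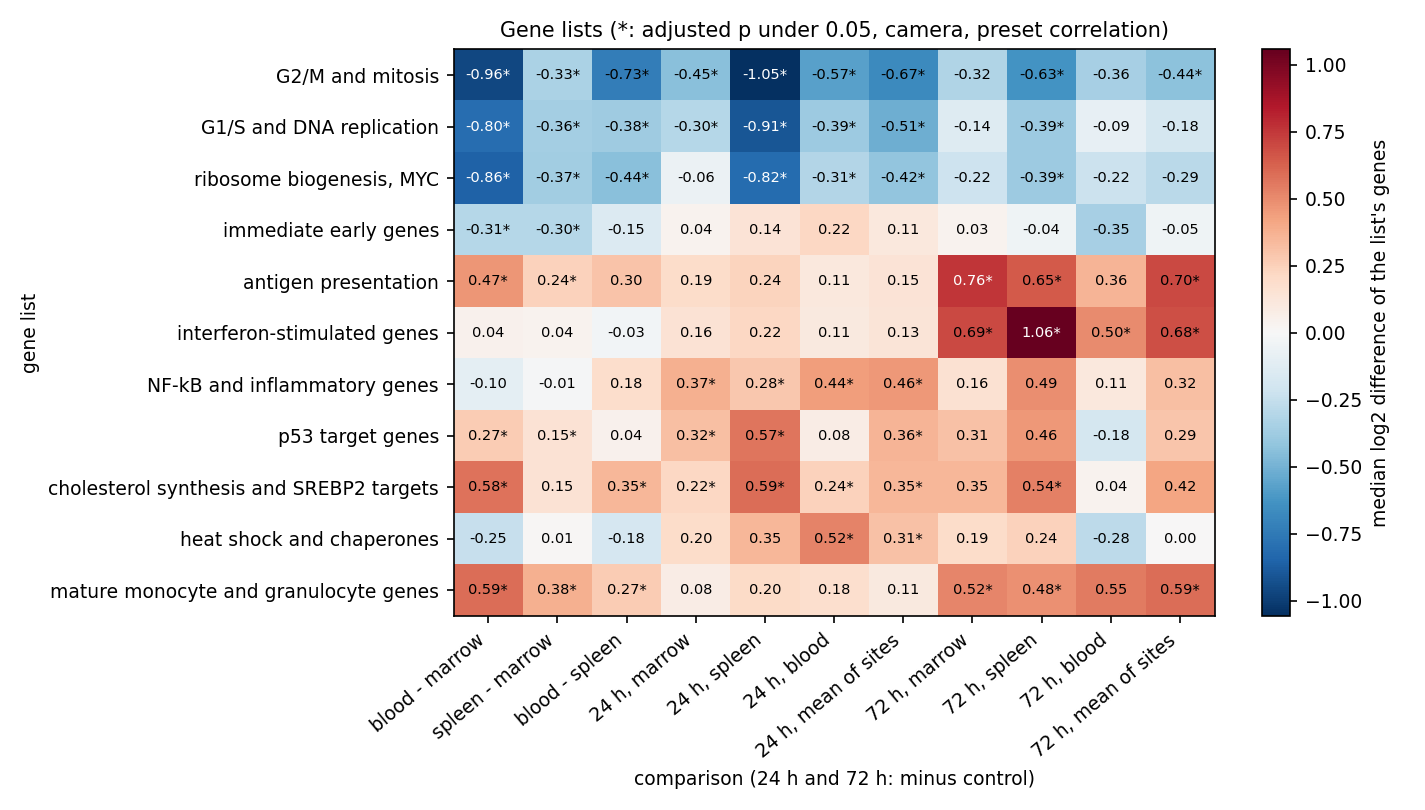
Heat map of the median log2 difference over the tested members of 11 gene lists (y axis) in 11 comparisons (x axis), blue for lower and red for higher, with a star where the camera test at the preset correlation passed; of 115 such calls over all lists and comparisons limma kept 0 with an estimated correlation (57 at an unadjusted p under 0.05). Mitosis genes were lower in blood (median -0.96 against marrow) and in 24 h spleen (-1.05), and interferon-stimulated genes were higher at 72 h (0.68 over all sites).

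At 72 h the list of interferon-stimulated genes passed at the preset correlation in each of the 3 sites, and in none of them with an estimated correlation or without mouse 9. In marrow 2 of 23 rose, 6 adjusted over the list alone, with a median of 0.69 (adjusted p = 0.00028, and adjusted p = 0.484 with estimated correlation; 0.77 and 0.68 in the covariate and BeadChip 2 fits). In spleen 2 of 23 rose, 9 higher and 1 lower adjusted over the list alone, with a median of 1.06 (adjusted p = 1.05e-05, and adjusted p = 0.396 with estimated correlation; 1.12 in both BeadChip fits). In blood 6 of 23 rose, 5 adjusted over the list alone, with a median of 0.50 (adjusted p = 0.0153, and adjusted p = 0.602 with estimated correlation; 0.64 and 0.68 in the BeadChip fits). ISG15 rose by 2.20 ± 0.43 in marrow, 2.37 ± 0.43 in spleen and 2.71 ± 0.43 in blood. Without mouse 9 the medians were 0.20, 0.33 and 0.15, at adjusted p = 0.328, 0.161 and 0.455, which were their highest over 15 alternatives with the estimated correlation left aside; the lowest were 6.25e-12, 1.88e-24 and 2.82e-06. Antigen presentation genes passed in marrow (median 0.76, 0 of 16 over all genes by limma, 9 adjusted over the list alone, adjusted p = 3.6e-05, and adjusted p = 0.278 with estimated correlation; 0.70 and 0.74 in the BeadChip fits) and in spleen (median 0.65, 0 of 16 over all genes, 4 adjusted over the list alone, adjusted p = 0.000611, and adjusted p = 0.278 with estimated correlation; 0.62 and 0.61 in the BeadChip fits). Their members with the smallest p were TAP1 (1.00 ± 0.27 in marrow and in spleen) and CD74 (1.55 ± 0.44 in marrow and 1.53 ± 0.44 in spleen).

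By site, marrow at 72 h showed rises of the pseudogene CYCSP52 (4.56 ± 0.63, on 1 of 3 control arrays, adjusted p = 0.000708), RETNLB (4.25 ± 0.89), ALAS2 (3.96 ± 0.86, on 1 of 3 control arrays), GNLY (3.74 ± 0.55) and H19, which was at least 19.4-fold higher (means 10.18 and 5.74). GASK1B (-2.72 ± 0.65), PACC1 (-2.69 ± 0.55), CERS6 (-2.43 ± 0.52) and LINC02910 (-2.38 ± 0.55) fell, and NCAM2, not detected in treated marrow, was at least 2.77-fold lower (4.95 and 7.46). In spleen HES4 (2.59 ± 0.58), CD14 (2.56 ± 0.38), CHST15 (2.54 ± 0.58), IFITM3 (2.53 ± 0.49) and the lectin CLEC10A (2.37 ± 0.47) rose. AMD1 (-2.77 ± 0.44), LINC02910 (-2.34 ± 0.55) and the ceramide synthase CERS6 (-2.33 ± 0.52) fell there, and DMRT3 and ME3, not detected in treated spleen, were at least 2.52-fold (5.04 and 7.27) and 2.29-fold (4.93 and 7.13) lower. In blood IFI27 (3.48 ± 0.84), RIMBP3 (3.23 ± 0.90), IFITM3 (2.92 ± 0.49) and S100A12 (2.72 ± 0.72) rose, and SCARNA2, not detected in control blood, was at least 5.42-fold higher (8.29 and 5.20). ZEB2 (-4.23 ± 0.86), RPL23 (-4.05 ± 1.52), HNRNPH2 (-3.77 ± 0.79) and HNRNPK (-3.21 ± 0.63) fell in blood, and AMD1 was at least 5.52-fold lower (5.50 and 8.52).

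In marrow 269 genes passed at 72 h (169 higher, 100 lower), 118 with the BeadChip covariate, 60 within BeadChip 2 and 2674 with the marrow arrays alone (1266 higher, 1408 lower). Without mouse 1, 2, 3, 4, 5, 6 or 8 the count was 174, 460, 964, 36, 42, 47 or 88. In spleen 89 passed (52 and 37), 27 with the covariate, 0 within BeadChip 2 (1895 at an unadjusted p under 0.05) and 12 with the spleen arrays alone. Without mouse 1, 2, 3, 5, 6 or 8 it was 48, 145 (70 higher, 75 lower), 1030 (492 and 538), 14, 6 or 11, without mouse 4 0 (1441 at an unadjusted p under 0.05) and without mouse 9 2707 (1252 and 1455). In blood 3499 passed (1432 and 2067), 3051 with the covariate, 2218 within BeadChip 2 and 0 with the blood arrays alone (3312 at an unadjusted p under 0.05). Without mouse 4, 5, 6 or 8 the blood count was 1676, 1372, 2299 or 841, and without blood replicate 8 alone it was 454. On the series matrix values 33.9% of the genes called in marrow were higher against 62.8%, 40.0% in spleen against 58.4%, and 14.8% in blood against 40.9%, with medians of all genes at -0.39, -0.20 and -0.43.

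**Figure D4:**
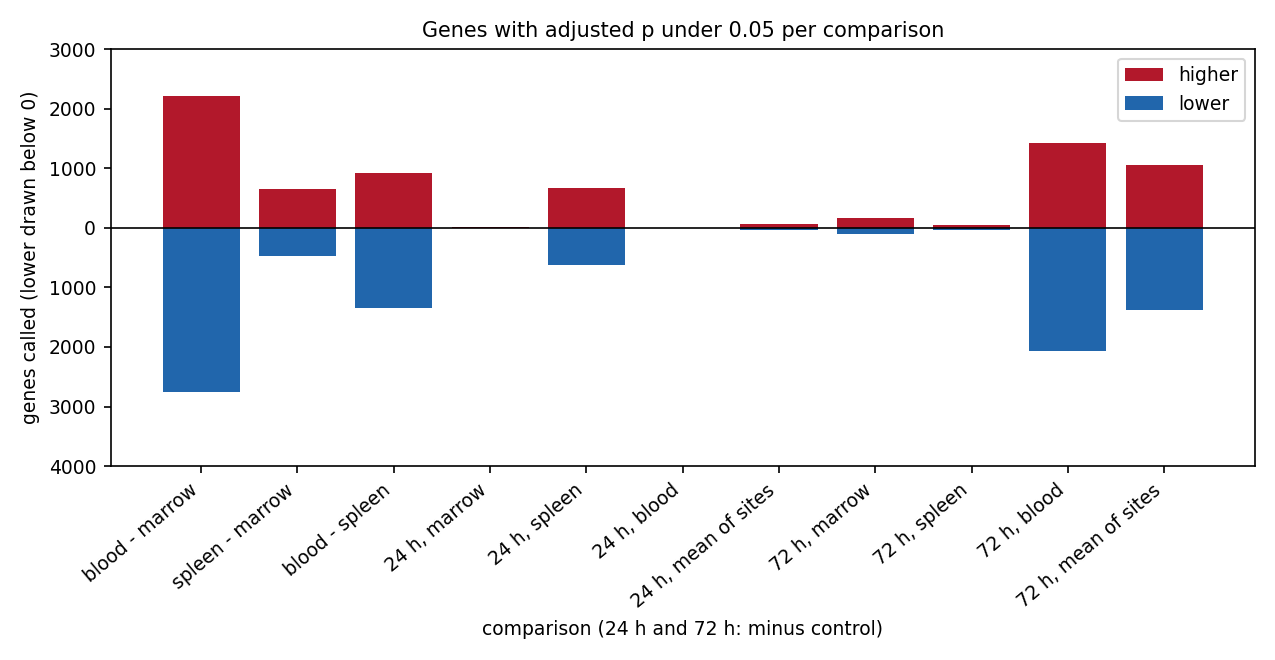
Number of genes past the threshold (y axis, genes higher drawn above 0 and lower below) in 11 comparisons (x axis). The tallest bars belong to blood against marrow, with 2219 higher and 2762 lower, and among treatment comparisons to 72 h blood, with 1432 higher and 2067 lower.

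The 72 h and 24 h groups were also set against each other, 2 mice against 3, on different BeadChips. MX1, an antiviral GTPase, was 5.33-fold higher at 72 h (2.41 ± 0.49, adjusted p = 0.0231) and ISG15 rose by 1.80 ± 0.30 (adjusted p = 0.02). EMP1 fell by 2.67 (SE 0.47, adjusted p = 0.02). The histone gene H2AC4 (2.34 ± 0.16), IGFBP5 (2.31 ± 0.36), HBD (2.17 ± 0.30, on 1 of 9 arrays at 24 h), CLEC10A (2.13 ± 0.30, on 4 of 9), PRTN3 (2.02 ± 0.37), ODAD3 (1.96 ± 0.49), IFI27 (1.95 ± 0.56) and IFITM3 (1.90 ± 0.35) rose. TPSG1, not detected at 24 h, was at least 2.02-fold higher (means 6.996 and 4.942). The kinase STK17B (-2.32 ± 0.36), ZEB2 (-2.29 ± 0.57), PCMTD2 (-2.27 ± 0.39), HNRNPH2 (-2.23 ± 0.53), PI15 (-2.16 ± 0.23, on 1 of 6 arrays at 72 h), ARMCX3 (-2.12 ± 0.45, on 2 of 6), HNRNPK (-2.12 ± 0.43), AMD1 (-2.10 ± 0.30) and HSD17B11 (-1.999 ± 0.476) fell.

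Interferon-stimulated genes rose from 24 h to 72 h in 7 of 23, 8 adjusted over the list alone, with a median of 0.55 (adjusted p = 0.00446, and adjusted p = 0.646 with estimated correlation) and 0.89 with the BeadChip covariate, IRF7 (0.84 ± 0.20) and IFI35 (0.56 ± 0.15) among them. Without mouse 9 the list did not pass (median 0.13, adjusted p = 0.666, and 2.12e-10 to 0.666 over 14 alternatives). Antigen presentation genes rose in 3 of 16, 3 adjusted over the list alone, with a median of 0.63 (adjusted p = 0.0315, and adjusted p = 0.391 with estimated correlation): TAPBP (0.69 ± 0.15), PSMB8 (0.86 ± 0.22) and CD74 (1.06 ± 0.32). They did not pass with the covariate (0.33, adjusted p = 0.178) or without mouse 2 (0.55, adjusted p = 0.122) or 8 (0.26, 0.0557), nor with probes detected on all arrays (0.086), with 0.00359 to 0.178 over 14 alternatives. Of 2147 genes that passed 963 were higher and 1184 lower at 72 h. With the BeadChip covariate limma called 0, with 1169 at an unadjusted p under 0.05. From marrow and spleen alone 3370 passed, 3287 with a random replicate block and 942 without the filter. Without mouse 1, 2, 3, 4, 5, 6 or 8 the count was 1, 3561, 1022, 377, 423, 195 or 9. From the series matrix values 371 passed, 24.3% of them higher against 44.9%, with a median of all genes at -0.18.

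Whether site differences depended on treatment was tested directly, with 1 adjusted p per gene for its blood and spleen differences from marrow together. EMP1 rose by 5.49 from marrow to blood in control mice, and that difference changed by -4.99 at 24 h (spleen minus marrow by -2.04, adjusted p = 0.00303 for both), since marrow reached 10.57 and blood was at 11.08 against 11.73. GNLY changed likewise by -3.38 (adjusted p = 0.0125) and CRIP2 by -3.52 (adjusted p = 0.0211). At 72 h EMP1 changed by -4.97 (adjusted p = 0.00782), with marrow at 8.26 and blood at 8.78. In all 31 genes passed at 24 h, 30 of them with a smaller gap between blood and marrow in treated mice, and 85 at 72 h, 52 of them with a smaller gap. Without a replicate block the counts were 2 and 4. On the BeadChip of the treated mice limma called 0 at 24 h (279 at an unadjusted p under 0.05) and 3 at 72 h. Without mouse 1, 2, 3, 4, 5 or 6 the 24 h count was 3, 4, 1159, 1, 1 or 1, and 116 without mouse 8 or 9. At 72 h it was 39 without mouse 1, 0 without mouse 4 or 5 (951 and 945 at an unadjusted p under 0.05), 3 without mouse 6, 10 without mouse 8, 1304 without mouse 9 and 15 without blood replicate 8 of the 72 h group.

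CXCR4 itself was abundant at each site, at 11.15 ± 0.05 (SD, n = 3) in control marrow, 11.07 ± 0.13 in spleen and 10.82 ± 0.18 in blood. Over the treatment groups it was lower in blood than in marrow (-0.64 ± 0.15, adjusted p = 0.00306), in 7 of 8 mice. Within BeadChip 1 (-0.61, adjusted p = 0.131) and BeadChip 2 (-0.49, 0.184) that difference did not pass (0.000255 to 0.184 over 18 alternatives). Spleen against marrow (-0.28 ± 0.15, adjusted p = 0.25) and blood against spleen (-0.36 ± 0.15, adjusted p = 0.0954) did not pass, except without mouse 9 (adjusted p = 0.0402 and 0.0438, and up to 0.887 and 0.72 over 18 alternatives). Within sites CXCR4 differed from control by -0.01 in marrow, -0.26 in spleen and -0.68 in blood at 24 h (adjusted p = 0.996, 0.67 and 0.347), and by -0.47, -0.82 and -0.73 at 72 h (adjusted p = 0.462, 0.176 and 0.127). From 24 h to 72 h it differed by -0.36 (0.334). In control mice blood minus marrow was -0.33, spleen minus marrow -0.08 and blood minus spleen -0.25 (adjusted p = 0.385, 1 and 0.594). At 72 h it passed over all sites with a random replicate block (-0.67, adjusted p = 0.0447) and in marrow with the marrow arrays alone (-0.47, 0.0423). It also passed without mouse 9, by -1.10 over all sites (adjusted p = 0.0184), -1.36 in spleen (0.0102) and -1.47 in blood (0.00308), and without mouse 8 blood stood at 0.02 (0.973); over the alternatives the adjusted p ran up to 0.585, 0.95 and 0.977. With every probe tested, a dimmer CXCR4 probe was lower in 24 h spleen (-0.95, adjusted p = 0.0124, up to 0.96 over 18 alternatives). It also fell in 72 h marrow (-1.21, 0.0195, up to 0.659). Its marrow and blood means were 7.155 and 6.564 in controls, 6.76 and 6.60 at 24 h and 5.94 and 7.16 at 72 h. CXCL12 was detected on 0 of 24 arrays by any of its 3 probes.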

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

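The tests of cell mixing, BeadChip, the 72 h blood array, RNA and globin signal were chosen only after the results they address were seen, and the tests of other splits of the samples were planned. Groups of 2 or 3 arrays were too small for a test of single arrays that stand apart.

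Site differences that changed with treatment were picked out by an F test over the blood and spleen differences from marrow together. At 24 h 31 genes passed, and at 72 h 85. Of the 10 splits of the 3 treated and 3 control mice, the real one gave 31 and the highest other 2, too few splits for a share under 0.05. The blood minus marrow difference was smaller at 24 h than in control mice for EMP1 (-4.986), H19 (-3.853), CRIP2 (-3.519), GNLY (-3.383) and the growth factor binding protein IGFBP3 (-3.244). H19 went from 5.74 to 9.70 in marrow and from 11.03 to 11.13 in blood. The difference, negative in control mice, rose for MOSPD3 (1.421), SLC27A5 (1.193), RNU105C (0.897) and PA2G4 (0.858), and 30 of the 31 gaps shrank. At 72 h the change was -5.507 for RETNLB, -4.969 for EMP1, -4.850 for CYCSP52, -4.685 for H19 and -4.601 for CD9. It was 3.241 for DHRS3, 2.602 for LY9, 2.370 for MIR142, 2.348 for MVB12B and 1.894 for SERPINB10, and 52 of the 85 gaps shrank. In at least 1 of the 4 groups compared, H19, IGFBP3 and RNU105C at 24 h and CYCSP52, H19, CD9, LY9, MVB12B and SERPINB10 at 72 h were detected on 0 arrays, so background limits the values of these genes.

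The rise of blood-associated genes in 24 h marrow was weighed first; both sides of it subtract the same 3 control marrow arrays, so low values there raise both. BeadChip stays open because BeadChip 1 held 1 control marrow array: over the 22 genes, chosen against all 3, control marrow differed by a median of 0.081 between BeadChips, and their median rise of 1.88 (median SE 0.313) was 1.94 (0.365) with the covariate and 1.91 (0.383) within BeadChip 1, where limma, with 12 arrays, called 0 (332 at an unadjusted p under 0.05) and with the covariate 9 of the 22. A share of cells from blood in treated marrow, at 19.8%, put 118 of 132 genes over 4-fold higher in control blood within 2 SE, with S100A10 above that level by 7.93 SE and SNORD3C below it by 4.15 SE. A common 41% of the log2 difference in every cell put 115 of 132 within 2 SE, so a mixture of cells and a shift within cells, which may follow release from the marrow niche, cannot be told apart, and 44 of the 132 also lay within 2 SE of control marrow. The harvest day stays open, since it equals the treatment group.

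The genes changed at 72 h were weighed against RNA amount or quality, for which no measured value was given in the sources used here, so the mean of 4 small RNA genes was assumed to follow it. Over the 24 arrays, as deviations from group means, the mean of 4 small RNA genes and the mean of the 1377 genes lower at 72 h correlated by r = -0.875 (permutation p = 0.001, adjusted 0.002) and rho = -0.774 (permutation p = 0.00638, adjusted 0.00638), with 100000 permutations and 2 tests in this family. The r was -0.842 without the 2 arrays farthest from the median, -0.886 within BeadChip 1, -0.899 within BeadChip 2, and -0.33, -0.894 and -0.95 in marrow, spleen and blood; arrays of 1 mouse are not independent. If that assumption holds, a difference in RNA may be a source of falls such as those of ZEB2 and HNRNPK, and a change of the small RNA genes themselves stays open. Blood replicate 8 of the 72 h group, without which 454 genes in 72 h blood passed, 385 of them among the 3499, and a treatment effect stay open.

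Globin and ALAS2 signal was weighed as a sign of red cells. HBA2 was detected on 24 arrays and ALAS2 on 13, while 3 of 13 other erythroid genes were detected on at least 3 arrays (HBD on 7, BPGM on 23 and FECH on 24). HBA1, AHSP, SLC4A1 and KLF1 were detected on 0 arrays and HBB on 2, which argues against human erythroid cells or an erythroid programme. Cross-hybridising mouse RNA may be a source that the sort on GFP and human CD45 would reduce; the dimmer HBA2 probe was detected on 2 arrays and the brighter on 24. Deviations of HBA2, HBD and ALAS2 correlated by 0.152 to 0.82 between genes, and without probe sequences this stays open.

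Other splits were counted for site and 24 h counts, not for 72 h. For the site averages, 1 of 100 splits, the real one itself, reached the real count, a share under 0.05. Blood and marrow gave 4981 (highest other 3510), spleen and marrow 1123 (451) and blood and spleen 2264 (1264). The control site differences allowed 4 splits, too few for a share under 0.05, with 1684, 58 and 593 against a highest other of 0 in limma. The 24 h comparisons allowed 10, too few as well, with 93 over the sites, 22 in marrow and 1295 in spleen against a highest other of 0. In blood 2 of 10 splits reached the real count of 4. With mice 1, 2 and 6 set against 3, 4 and 5, 148 genes passed. On PC1 blood of mice 3, 4 and 5 lay from -23.4 to -10.2, and of 1, 2 and 6 from 10.4 to 59.2.

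Probes without a gene symbol were in no comparison of the report and gave a signal. Of 3841 such probes, 1 was higher over the sites at 24 h and limma called 0 lower, with 478 at an unadjusted p under 0.05. At 72 h 132 were higher and 157 lower, with 1309 at an unadjusted p under 0.05. What they measure was not given in the sources used here.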

How the results depend on the processing

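Alternatives chosen only after the results were seen are listed above, under how the data were processed. Over 7296 values for 427 results on named genes, 5832 had the direction and side of the threshold first reported, 1340 lost the threshold, 116 gained it and 8 changed direction. For 52 list results these numbers were 705, 90, 1 and 0 of 796. Of 310 gene and list counts 144 lay within 1.5 times the first value. All 21 named genes past the threshold between blood and marrow, GNLY, CD14 and EGR1 among them, passed without each mouse, and 17 under every alternative. In the 24 h mean over the sites 0 of 20 did in limma, and in the 72 h mean 0 of 20, where 1901 and 4443 genes had an unadjusted p under 0.05. Where no cause is named below, the cause was not tested.

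On the series matrix values counts were 2997 for blood against marrow, 404 for spleen against marrow, and 398, 18 and 24 for the control differences of blood and marrow, spleen and marrow, and blood and spleen. They were 0 for 24 h over the sites (limma, 1537 at an unadjusted p under 0.05), 371 for 72 h against 24 h, 9, 189 and 2 for 24 h marrow, spleen and blood, and 56, 5 and 1481 for 72 h. For treatment by site they were 4 at 24 h and 0 at 72 h (497 at an unadjusted p under 0.05). Without background correction counts were 142 for 24 h over the sites, 12 in 24 h marrow, 9 in 24 h blood and 56 for treatment by site at 72 h. With no filter they were 912 for 72 h, 942 for 72 h against 24 h, 8 in 24 h blood and 47 for treatment by site at 72 h. With probes detected on all arrays, which tests fewer genes, they were 38 for control spleen and marrow, 7 in 24 h blood and 38 for treatment by site at 72 h.

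With no replicate block counts were 505 for spleen against marrow, 892 for blood against spleen, 1037, 16 and 171 for the control differences, and 2 and 4 for treatment by site. A random replicate block gave 543 for 24 h, 3287 for 72 h against 24 h, and 66 for treatment by site at 24 h. Within BeadChip 1, with fewer mice, the site averages gave 710, 15 and 5, and within BeadChip 2 1738, 29 and 182, in the order blood and marrow, spleen and marrow, blood and spleen. Control differences within BeadChip 2 gave 510, 13 and 41.

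With the BeadChip as a covariate limma gave 0 for 24 h (1024 at an unadjusted p under 0.05), 1 for 72 h, 0 for 72 h against 24 h (1169), 10 in 24 h marrow, 1 in 24 h blood, 118 in 72 h marrow and 27 in 72 h spleen. On the BeadChip of the treated mice, with fewer mice, it gave 0 for 24 h (686), 0 for 72 h (3787), 0 in 24 h marrow, spleen and blood (332, 1216 and 502), 60, 0 (1895) and 2218 in 72 h marrow, spleen and blood, and 0 (279) and 3 for treatment by site. With the arrays of 1 site alone counts were 519, 812 and 0 (664) in 24 h marrow, spleen and blood, and 2674, 12 and 0 (3312) at 72 h. From marrow and spleen only they were 1204 for 24 h and 3370 for 72 h against 24 h.

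Leaving out each mouse, or blood replicate 8 of the 72 h group, gave 3759 to 5434 for blood against marrow, 508 to 1464 for spleen against marrow and 794 to 3080 for blood against spleen. The control differences ranged from 309 to 2246, 17 to 74 and 14 to 1032. Over the sites the 24 h count ranged from 0 (1162) to 345, the 72 h count from 0 (3347) to 3827 and that of 72 h against 24 h from 1 to 3561. Ranges were 7 to 62, 339 to 1763 and 0 (742) to 1668 in 24 h marrow, spleen and blood. At 72 h they were 36 to 964, 0 (1441) to 2707 and 454 to 4243. For treatment by site they were 1 to 1159 and 0 (945) to 1304. A fit that left 1 mouse at 72 h assumed that it varied like the other groups. The report names the mouse for each count that moved by over 1.5 times.

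The 115 list calls fell to 0 with an estimated correlation in camera of limma, with 57 at an unadjusted p under 0.05, and ranged from 90 without mouse 9 to 116 without mouse 3. Mitosis, G1/S and ribosome biogenesis lists passed under each alternative with a value, the estimated correlation aside. The 8 changes of direction were all of CXCR4, which passed in none of them: 0.0194 for control spleen and marrow within BeadChip 2 and without mouse 4 (down to -0.143 without others, adjusted p 0.999 to 1 over 17 alternatives), 0.07167 for 72 h against 24 h without mouse 8 (down to -0.787, 0.0512 to 0.881), and 0.07808 and 0.01426 in 24 h marrow without mouse 2 or 4 (down to -0.07642, 0.693 to 1). In 72 h blood they were 0.5961 with every probe tested and 0.02161 without mouse 8 or its blood array (down to -1.474, 0.00308 to 0.977, where it passed without mouse 9). Signal near background limits genes such as RASL11B and IL19, given in blood as bounds.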

Other observations

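Further lists passed that stand outside the main account, and all of them were chosen for mention only after the result was seen. Unfolded protein response genes, which expand the folding capacity of the endoplasmic reticulum, were lower in blood than in marrow in 10 of 16 cases, 10 adjusted over the list alone (median -0.32, adjusted p = 0.0278, and adjusted p = 0.426 with an estimated correlation). The transcription factor XBP1 fell by 1.09, the disulfide isomerases PDIA6 by 0.95 and PDIA4 by 0.45, and the chaperone DNAJB11 by 0.38. The list did not pass without mouse 9 (adjusted p = 0.0579, and 0.00101 to 0.0579 over 14 alternatives). Target genes of p53 had 7 higher and 1 lower of 17, 7 and 1 adjusted over the list alone (median 0.27, adjusted p = 0.039, and adjusted p = 0.484 with an estimated correlation). CDKN1A (1.37 ± 0.16), TP53INP1 (1.10 ± 0.19) and PHLDA3 (0.84 ± 0.21) rose and TIGAR fell (-0.70 ± 0.20). This list did not pass without mouse 3, 6 or 9, at adjusted p = 0.0945, 0.05 and 0.116 (median 0.16 without mouse 9), nor on the series matrix values (0.09, 0.0777) or with probes detected on all arrays (0.0567, and 0.0214 to 0.116 over 14 alternatives).

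Between blood and spleen, TGF-beta and BMP response genes were higher in blood in 5 of 11 cases, 6 adjusted over the list alone (median 0.41, adjusted p = 0.0124, and adjusted p = 0.328 with an estimated correlation). The matricellular gene CCN2 (0.99 ± 0.16), the differentiation inhibitor ID2 (0.76 ± 0.16) and LTBP3 (0.41 ± 0.12) rose, and KLF10, not detected in spleen, was at least 1.02-fold higher (means 5.93 and 5.34). The list did not pass without mouse 3 (median 0.42, adjusted p = 0.0708) or 8 (0.21, 0.138), nor without blood replicate 8 of the 72 h group (0.24, 0.0521), with 0.00205 to 0.138 over 14 alternatives. After 24 h over the sites, NRF2 oxidative stress and heme response genes were higher in 2 of 13, 2 adjusted over the list alone. Their median was 0.23 (adjusted p = 0.00756, and 0.324 with an estimated correlation). It was 0.27 in both BeadChip fits, the same by design. HMOX1 (1.65 ± 0.18) and the NADPH-producing malic enzyme ME1 (1.37 ± 0.17) rose, while GCLM (0.41 ± 0.19) and PGD (0.49 ± 0.23) did not pass. With probes detected on all arrays the list did not pass (adjusted p = 0.102, and 0.00138 to 0.102 over 15 alternatives).

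Genes chosen without reference to control marrow were also followed into 24 h marrow. Of 24 genes over 4-fold higher in control blood than in control spleen, 18 lay above control marrow at 24 h by over 2 SE, with a median difference of 1.18. Of the 22 genes higher in 24 h marrow 16 were among the 378 higher in control blood than in control spleen, where independent lists would share 0.8; both use the same control mice.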
